A study of Homo sapiens with 8 samples.

How the data were processed

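The labels describe 8 cultures of the human hepatocellular carcinoma lines Hep3B and Huh7.5.1, each kept for 48 h with DMSO or with 10 μM CU27, with 2 biological replicates per line and treatment. Hep3B replicates carry the numbers 2 and 3, and Huh7.5.1 replicates the numbers 1 and 2. Total RNA was labelled with biotin by a 3′ in vitro transcription kit and hybridised to 1 Affymetrix expression array per sample, per the labels. The values used were the deposited value table of 49395 probe sets and 8 columns, as deposited by the authors. The deposited signals were taken as log2 transformed before deposition, which was read from the range of the values because the labels do not state it. MAS5 is named, with no version, in the submitters' processing notes. The rule that scaled the arrays to each other is not given in the sources used here and stays unknown, as does any centring between the lines. The column medians in log2 units were 5.85 and 5.82 for Hep3B DMSO, 5.86 and 5.85 for Hep3B CU27, 6.27 and 6.23 for Huh7.5.1 DMSO, and 6.26 and 6.25 for Huh7.5.1 CU27. Scanner files were not analysed here.

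Both Hep3B CU27 columns were exact linear functions of the 2 Hep3B DMSO columns at all 49395 probe sets, to a tolerance of 1e-06, so they held no measurement of their own. The design fixed before the data were examined fitted all 8 columns. After this relation was seen, the 6 other arrays became the basis of every comparison, and the fit of all 8 columns was kept as an alternative. The effect of CU27 in Hep3B, the effect over both lines, the difference of the effect between lines, and the correlation and overlap of the effects were therefore not reported as results. The difference between lines in DMSO and the effect of CU27 in Huh7.5.1 remained.

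Of the probe sets, 102 were array controls and were left out. The platform annotation gave 44988 probe sets exactly 1 gene symbol, 1832 several and 2473 none. Only those with 1 symbol were named, and 44961 of them matched the gene table by Entrez identifier, with 0 symbols changed. Each of the 18132 genes was represented by its probe set with the highest mean signal. A total of 11734 genes had more than 1 probe set. Among the genes named for CU27, RRP1B, RAD51C, HSPA5, ANKRD37, IGF2BP1, ORM1, GPNMB and DDIT3 had at least 1 other probe set with a CU27 change of the opposite sign. Genes named between lines had 0 probe sets whose difference between lines was of the opposite sign on the deposited scale, and relative to the shift MT2A and TGFB2 each had 1. A bound on a fold holds for the probe set used. A gene was tested when its mean reached the floor, log2 6.11, in at least 1 group. The floor was the 50th percentile of the values of all probe sets that were not controls, and 11383 genes reached it. Where a group mean lay below the floor, the fold is written as at least the ratio to the floor. Array data carry no read depth, so the number of arrays limits the precision.

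Group means were compared with limma 3.58.1 in R 4.3.3, using lmFit, contrasts and eBayes with an intensity trend over the 6 arrays. The fit had 3 residual degrees of freedom and 5.87 prior degrees of freedom. P-values were two-sided and adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. An exact permutation test of 2 arrays against 2 cannot go below a p of 0.333, so none was used. Errors are standard errors from limma, with n = 2 arrays per group. Gene lists were compared with all other genes by camera with a preset correlation of 0.01, adjusted over the lists of a comparison. The 37 lists held 805 members, of which 740 were on the array, and lists with at least 5 tested genes were tested. Some lists share genes, such as HP, FGA, FGB and FGG in the secreted protein and acute phase lists. Results of such lists are not independent. Each list was also tested with a correlation estimated from the data and with fry.

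Genes were named by a rule fixed with the design. It took the 10 largest rises and 10 largest falls with CU27 among genes past the test whose CU27 arrays both lay on the same side of both DMSO arrays, ranked after raising group means to the floor. It took the 8 largest differences each way between lines and up to 3 members of each list past the camera threshold, by smallest p in the direction of the list. It also took MYC, AFP, ALB, MKI67, CDKN1A, DDIT3, HMOX1 and CYP1A1 where tested, and skipped unnamed and antisense symbols. A further gene of the rule is not reported here. Other genes are given only as members of these lists.

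The procedure was tested on data simulated for the Huh7.5.1 comparison over 11383 genes, of which 200 were changed. It recovered 95% of the 2-fold and 100% of the 4-fold changes, called 0.161% of unchanged genes, and 8.04% of its calls were false. A list of 30 genes shifted by 0.5 had a camera adjusted p of 3.99e-24, and 0 of 34 unshifted lists were called. With an estimated correlation the shifted list had an adjusted p of 0.234, so that version missed a shift of this size. Genes varied independently of each other in the simulation, and the unshifted lists were drawn at random. The simulation therefore does not test either version on lists whose genes vary together.

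The alternatives were quantile normalization, centring of each array on its median, no filter, a floor at the 75th percentile, a pseudocount equal to the floor, and values raised to the floor. Others were the mean of all probe sets of a gene, leaving out probe sets with an _x_at or _s_at suffix, eBayes without the trend, robust eBayes, and a fit of the 4 arrays compared. The last were a block for the replicate number and leaving out each array in turn. Leaving out an array leaves a single array in its group and fewer residual degrees of freedom. A call lost there need not mean a smaller change. Figures and checks of the columns used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.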

Results

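Gene expression was profiled in Hep3B and Huh7.5.1 cells, established human hepatocellular carcinoma lines, after 48 h with 10 μM CU27 or with the solvent DMSO. CU27 is known here only by its code name, and the series asks which transcripts it alters in liver cancer cells. Measured values of 6 arrays entered the comparisons, 2 each for Hep3B DMSO, Huh7.5.1 DMSO and Huh7.5.1 CU27. Pearson correlations over probe sets within these groups were 0.994, 0.993 and 0.991. The difference between 3′ and 5′ control probe sets of ACTB, a measure of RNA integrity, was 2.28 and 1.60 log2 units in Hep3B DMSO, 0.94 and 1.06 in Huh7.5.1 DMSO, and 0.98 and 1.21 in Huh7.5.1 CU27.

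The Hep3B columns gave no separate reading of CU27-treated cells. At all 49395 probe sets, the CU27 replicate 3 column equalled 2 times DMSO replicate 2 minus DMSO replicate 3, within 1e-06. The CU27 replicate 2 column equalled 3 times DMSO replicate 2 minus 2 times DMSO replicate 3, within the same tolerance. The mean difference between CU27 and DMSO in Hep3B was therefore 2 times the difference between the DMSO replicates, with a correlation of 1.0 over probe sets. The matching correlation in Huh7.5.1 was 0.191. No gene is reported as changed by CU27 in Hep3B. The DMSO columns of Hep3B held exactly equal values at 1086 probe sets, against 0 in each of the other 14 pairs of the 6 columns used, for a reason not known here. Elsewhere they differed, with an SD of 0.27 over probe sets for their difference and of 0.28 in Huh7.5.1 DMSO. Equal values affected 126 tested genes, of which 18 passed the test with CU27 in Huh7.5.1, or 13 when only Huh7.5.1 arrays were fitted, and 76 between lines.

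**Figure D1:**
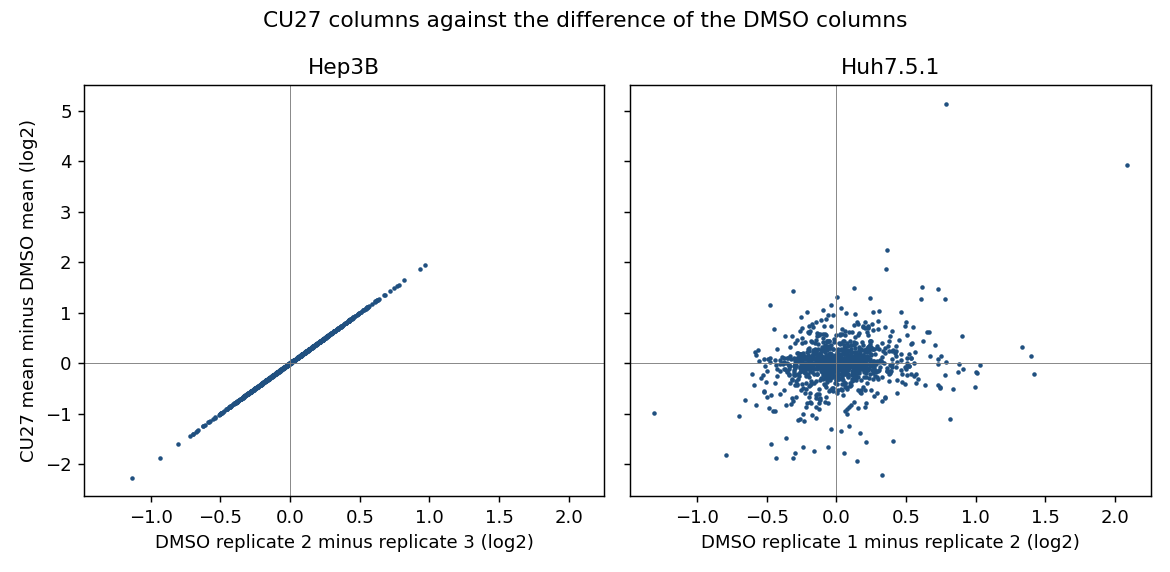
CU27 mean minus DMSO mean (y axis, log2 units) against the difference between the DMSO replicates (x axis, log2 units) for 988 probe sets per line, with a panel for each line. In Hep3B the points lie on a straight line, and in Huh7.5.1 they scatter, with correlations of 1.0 and 0.191 over all probe sets.

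CU27 changed 2809 of 11383 tested genes in Huh7.5.1 (limma, adjusted p threshold 0.05), of which 1429 rose and 1380 fell. Metallothionein, heat shock, cholesterol synthesis, hypoxia and interferon genes were among those that rose, while mitotic, amino acid stress, liver secretory and chemokine genes were among those that fell. Changes of at least 2-fold were found for 337 genes that rose and 343 that fell, and of at least 4-fold for 41 and 24. Of the 35 lists tested, 18 passed camera, 8 upward and 10 downward, and 0 passed with an estimated correlation. The version with an estimated correlation missed a shift of 0.5 simulated in genes that varied independently. Correlations estimated in the data reached 0.636, in the heat shock list, so the simulation does not decide between the versions. A high correlation does not alone account for the lost calls. In the G2/M list the estimate was 0.016, yet the unadjusted camera p went from 3.32e-11 to 0.00833. With 3 residual degrees of freedom, 0 passes with an estimated correlation do not show that the lists were unchanged. By fry, which tests whether a list moves on balance in a single direction, 17 lists passed, of which 12 were among the 18. The other 5 were lists that camera did not pass, with p53, YAP/TEAD, fatty acid oxidation and hepatocyte metabolism genes downward and leukocyte markers upward. The medians of hepatocyte metabolism genes and leukocyte markers were -0.27 and 0.16, but both were 0 with group means raised to the floor. Under fry the calls of the MYC target, ribosome biogenesis, DNA replication, repair, heat shock and acute phase lists were lost. The CU27 and DMSO values did not overlap for 63.8% of genes, against 33.3% by chance. The number of changed genes depended on single arrays, being 1639 without DMSO replicate 1, 900 without DMSO replicate 2 and 1517 without CU27 replicate 2.

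Metallothionein genes, which encode small metal-binding proteins, made up 6 of the 10 largest rises in CU27-treated Huh7.5.1 cells. MT1B rose by 6.65 ± 0.28 on the log2 scale (SE, n = 2 arrays per group, limma adjusted p = 1.5e-05). MT1M rose by 5.48 ± 0.47, MT1G by 4.10 ± 0.33 and MT1F by 3.31 ± 0.31. MT1H and the pseudogene MT1JP lay below the floor in DMSO and rose at least 21.3-fold and at least 27.7-fold. All 8 measured members of the metallothionein and zinc export list rose, also when adjusted over the list alone, and they included the zinc exporter SLC30A1 at 0.62 ± 0.13. The list had a median of 2.88 and a camera adjusted p of 5.26e-08, with adjusted p = 0.402 with an estimated correlation. Metallothionein transcripts are nearly identical in sequence, so the level of each single member is uncertain.

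**Figure D2:**
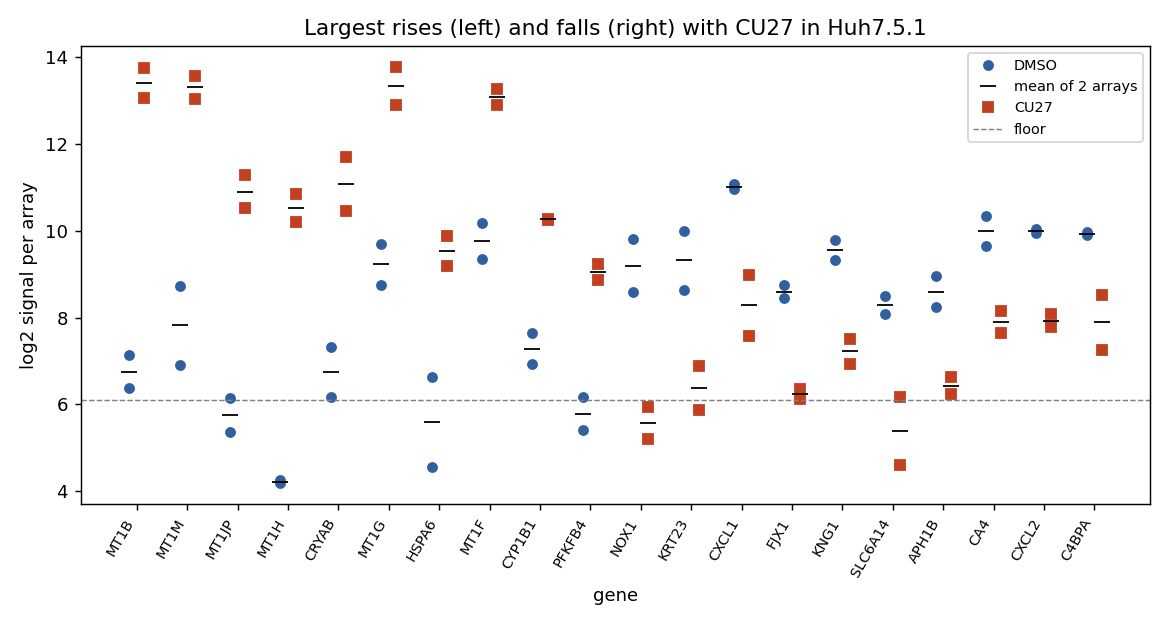
Log2 signal (y axis) of the 20 genes with the largest rises and falls in CU27-treated Huh7.5.1 cells (x axis), with a point for each DMSO and CU27 array and a dashed line at the floor of 6.11. For every gene shown, the CU27 points lie on the same side of both DMSO points.

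Some heat shock genes rose. CRYAB, a small heat shock protein, rose by 4.34 ± 0.43 (limma adjusted p = 0.000658), while its other probe set lay below the floor, with a value of 0.11. HSPA6, an inducible HSP70 that lay below the floor in DMSO, rose at least 10.7-fold. Of 17 measured members of the cytosolic heat shock list, 6 rose and 2 fell, or 8 and 2 adjusted over the list alone. HSPA1B rose by 2.28 ± 0.41 and the co-chaperone BAG3 by 1.01 ± 0.27, and HSPA1B is uncertain because HSPA1A is nearly identical to it. SERPINH1 and HSPA4 were the members that fell. The list had a camera adjusted p of 0.0246, with adjusted p = 0.674 with an estimated correlation. Its call was lost without DMSO replicate 2 (adjusted p = 0.156), without CU27 replicate 2 (adjusted p = 0.138) and in 3 further alternatives, over a range of 0.000344 to 0.233. BAG3 was no longer past the test in 6 of 18 alternatives, with adjusted p from 0.00583 to 0.172, among them each Hep3B array, DMSO replicate 2 and CU27 replicate 2 left out.

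Some endoplasmic reticulum chaperone genes rose, and many stress genes of amino acid metabolism fell. Among the endoplasmic reticulum chaperones, 6 of 20 rose and 1 fell, or 8 and 1 adjusted over the list alone. The co-chaperone DNAJB9 rose by 0.99 ± 0.17, the ubiquitin ligase SYVN1 by 0.57 ± 0.14 and the chaperone HSPA5 by 0.27 ± 0.07, and XBP1, a transcription factor of the unfolded protein response, fell by 0.62. Of 31 measured genes of the integrated stress response under ATF4, 18 fell and 0 rose, or 20 and 0 adjusted over the list alone. The transcription factor CEBPG fell by 1.07 ± 0.14, the serine pathway enzyme SHMT2 by 0.99 ± 0.13 and the secreted glycoprotein STC2 by 1.07 ± 0.15. DDIT3, the stress-induced factor CHOP, had a value of -0.00 ± 0.26 and was not past the test. The chaperone list had a camera adjusted p of 0.0258, with adjusted p = 0.402 with an estimated correlation, and the ATF4 list one of 2.06e-07, with adjusted p = 0.402 with an estimated correlation. The chaperone call was lost without CU27 replicate 1 (adjusted p = 0.067) and in 2 further alternatives, over a range of 0.00737 to 0.067, and 1 of 6 HSPA5 probe sets had a value of -0.88. SYVN1 and HSPA5 were no longer past the test without DMSO replicate 1, DMSO replicate 2 or CU27 replicate 2. With the mean of all probe sets their limma adjusted p was 0.0991 and 0.715.

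Most cholesterol synthesis genes rose. The cholesterol pathway enzyme SQLE rose by 1.70 ± 0.12 (limma adjusted p = 0.000307), INSIG1, which retains the SREBP complex in the endoplasmic reticulum, by 2.64 ± 0.19, and the final-step enzyme DHCR7 by 1.52 ± 0.12. Of 20 measured members of the cholesterol synthesis and uptake list, 14 rose and 1, the sterol reductase TM7SF2, fell, or 15 and 1 adjusted over the list alone. The list median was 0.82, or 0.81 with group means raised to the floor, and the camera adjusted p was 1.86e-07, with adjusted p = 0.350 with an estimated correlation.

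Most genes of hypoxia and glycolysis also rose. The glycolytic aldolase ALDOC rose by 2.20 ± 0.15 (limma adjusted p = 0.000307), ANKRD37, a target of the hypoxia-inducible factor, at least 2.83-fold, and PFKFB4, a regulator of glycolytic flux, at least 7.71-fold. Of 25 measured members, 19 rose and 0 fell, or 19 and 2 adjusted over the list alone. The median was 0.98 and the camera adjusted p was 3.47e-08, with adjusted p = 0.402 with an estimated correlation. The other probe set of ANKRD37 lay below the floor, with a value of -0.06, and the weakest of PFKFB4 had a value of 0.91.

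Interferon and antigen presentation genes rose in part. The ubiquitin-like protein ISG15 rose by 2.16 ± 0.15. The peptide transporter TAP1 and the immunoproteasome subunit PSMB9 lay below the floor in DMSO and rose at least 3.13-fold and at least 4.21-fold by the probe set used, while their weakest other probe sets had log2 values of 1.19 and 0.22. Of 21 measured members, 11 rose and 0 fell, or 13 and 0 adjusted over the list alone. The median was 0.73, or 0.60 with group means raised to the floor. The camera adjusted p was 1.13e-06, with adjusted p = 0.406 with an estimated correlation.

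Several lysosome genes and a few targets of the aryl hydrocarbon receptor rose. The protease CTSB rose by 0.80 ± 0.12, RRAGD, a GTPase that signals nutrients to mTORC1, by 1.90 ± 0.31, and the membrane glycoprotein GPNMB by 1.00 ± 0.18. In the autophagy and lysosome list 12 of 23 members rose and 1, the autophagy receptor SQSTM1, fell, or 15 and 1 adjusted over the list alone. The list had a camera adjusted p of 5.02e-05, with adjusted p = 0.402 with an estimated correlation. The cytochrome CYP1B1 rose by 2.97 ± 0.22 (5 probe sets, from 0.56 to 3.21) and TIPARP, a repressor of the receptor, by 1.16 ± 0.12. They were the 2 of 6 receptor targets that rose, with 0 that fell, or 2 and 1 adjusted over the list alone. CYP1A1 had a value of 0.73 ± 0.31 and was not past the test (limma adjusted p = 0.120). The receptor list had a median of 0.52, or 0.45 with group means raised to the floor, and a camera adjusted p of 0.0413, with adjusted p = 0.402 with an estimated correlation. The call of the receptor list was lost in 8 of 19 alternatives, over a range of 0.0092 to 0.112, including without DMSO replicate 1 (adjusted p = 0.0685), CU27 replicate 1 (adjusted p = 0.067) and CU27 replicate 2 (adjusted p = 0.0766). Without DMSO replicate 2, GPNMB had an adjusted p of 0.0559 (range 0.00215 to 0.0559 over alternatives) and CYP1A1 one of 0.0385 (range 0.004 to 0.613).

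Many mitotic genes fell. HMMR, a spindle-associated protein, was 2.84-fold lower (SE 0.18 on the log2 scale), the cyclin CCNB2 fell by 1.08 ± 0.12 and the ubiquitin-conjugating enzyme UBE2C by 1.00 ± 0.09. Of 29 measured genes of G2/M and mitosis, 17 fell and 0 rose, or 22 and 0 adjusted over the list alone. MKI67, a widely used proliferation marker, had a value of -0.07 ± 0.16 and was not past the test, and its 6 probe sets ran from -0.95 to -0.00. The list median was -0.67 and the camera adjusted p was 1.16e-09, with adjusted p = 0.292 with an estimated correlation.

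Some DNA replication and repair genes fell. Among 28 replication and G1/S genes, 7 fell and 1 rose, both over all genes and adjusted over the list alone. The replication licensing factor CDC6 fell by 0.69 ± 0.12, the polymerase subunits POLE2 by 0.77 ± 0.16 and POLA1 by 0.83 ± 0.18, and the transcription factor E2F1 rose by 0.81 ± 0.16. Of 14 genes of homologous recombination and repair, 3 fell and 0 rose, likewise adjusted over the list alone. These were RAD51C at -0.86 ± 0.14, PALB2 at -0.71 ± 0.18 and BRCA1 at -0.54 ± 0.15. The replication list had a median of -0.24 and a camera adjusted p of 0.0350, with adjusted p = 0.644 with an estimated correlation, and the repair list a median of -0.33 and a camera adjusted p of 0.0258, with adjusted p = 0.632 with an estimated correlation. Without DMSO replicate 1 or CU27 replicate 2 the replication list had adjusted p of 0.262 and 0.251 (range 0.00409 to 0.262) and the repair list 0.146 and 0.0974 (range 0.00508 to 0.146). Calls of POLE2, POLA1, PALB2 and BRCA1 were each lost without DMSO replicate 2 and, for the last 3, without DMSO replicate 1. Those of PALB2 and BRCA1 were also lost without CU27 replicate 1, and those of POLA1 and BRCA1 without CU27 replicate 2. Some were lost although the change was larger. POLA1 and PALB2 were at -0.85 and -0.78 without DMSO replicate 1, and BRCA1 at -0.59 without CU27 replicate 1. Others shrank, such as POLA1 at -0.66 and BRCA1 at -0.49 without CU27 replicate 2. Without _x_at and _s_at probe sets BRCA1 was at -0.22 (limma adjusted p = 0.395).

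MYC, some MYC targets and some ribosome biogenesis genes fell. MYC, a transcription factor that drives growth, fell by 0.56 ± 0.13 (limma adjusted p = 0.0138). Of 28 measured MYC targets, 8 fell and 3 rose, or 10 and 3 adjusted over the list alone. The snoRNP protein NOP56 fell by 0.95 ± 0.10, the kinase CDK4 by 0.65 ± 0.09 and the pseudouridine synthase DKC1 by 0.90 ± 0.13, while LDHA, TFRC and HSPE1 rose. Of 25 ribosome biogenesis genes, 9 fell and 2 rose, or 12 and 2 adjusted over the list alone. The RNA polymerase I subunit POLR1B fell by 0.65 ± 0.14, the ribosome assembly factor GRWD1 by 0.71 ± 0.16 and RRP1B, a nucleolar protein, by 0.53 ± 0.13. The MYC target list had a camera adjusted p of 0.0210, with adjusted p = 0.608 with an estimated correlation, and the ribosome biogenesis list one of 0.00606, with adjusted p = 0.519 with an estimated correlation. Without DMSO replicate 2 MYC had an adjusted p of 0.115 (range 0.00526 to 0.115), the MYC target call was lost without DMSO replicate 1 (adjusted p = 0.0821), without CU27 replicate 1 (adjusted p = 0.0705) and by fry (adjusted p = 0.0775), over a range of 0.00485 to 0.0821, and the ribosome biogenesis call by fry (adjusted p = 0.0673), over a range of 0.000599 to 0.0673. The other RRP1B probe set had a value of 0.40, and with the mean of all probe sets RRP1B was at -0.07 (limma adjusted p = 0.804). Limma adjusted p was 0.118 for POLR1B without _x_at and _s_at probe sets and 0.101 for GRWD1 in the fit of all 8 columns. Calls were also lost without single arrays for RRP1B (DMSO replicate 2 and CU27 replicate 2), GRWD1 (DMSO replicates 1 and 2) and POLR1B (DMSO replicate 2).

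Many liver secretory genes and some fetal liver genes fell. The plasma glycoprotein AHSG fell by 1.40 ± 0.12 (limma adjusted p = 0.000394), the kinin precursor KNG1 by 2.33 ± 0.23 and the hyaluronan-binding ITIH2 by 1.06 ± 0.11. Of 25 measured hepatocyte secreted proteins, 16 fell and 0 rose, or 20 and 0 adjusted over the list alone. ALB, the gene for serum albumin, had a value of -0.10 ± 0.06 and AFP, the fetal alpha-fetoprotein, one of -0.23 ± 0.14, neither past the test. Of 16 fetal liver and cancer stem cell markers, 7 fell and 1 rose, or 9 and 1 adjusted over the list alone. The biliary and progenitor transcription factor SOX9 fell by 1.36 ± 0.11, the RNA-binding IGF2BP1 by 0.86 ± 0.12 and PROM1, the CD133 antigen, by 0.81 ± 0.13, while the hyaluronan receptor CD44 rose by 1.93. The secretory list had a median of -0.69, or -0.67 with group means raised to the floor, and a camera adjusted p of 5.24e-08, with adjusted p = 0.419 with an estimated correlation. The fetal list had a median of -0.40 and a camera adjusted p of 0.00677, with adjusted p = 0.402 with an estimated correlation. AFP had an adjusted p of 0.00886 without CU27 replicate 1 (range 0.00886 to 0.887 over alternatives), and 1 of 3 IGF2BP1 probe sets had a value of 0.44.

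Several chemokine and acute phase genes fell. The neutrophil chemokines CXCL1, CXCL2 and CXCL8 fell by 2.73 ± 0.36, 2.07 ± 0.15 and 1.77 ± 0.24, and CXCL1 and CXCL2 are uncertain because they resemble each other and CXCL3. Of 16 NF-kB and inflammatory genes, 7 fell and 3 rose, or 10 and 3 adjusted over the list alone, and those that rose were the transcription factors IRF1, RELB and NFKB2. The siderophore-binding LCN2 lay below the floor in CU27 and fell at least 2.41-fold, and the near-identical acid glycoproteins ORM1 and ORM2, whose single levels are uncertain, had log2 changes of -1.15 ± 0.13 and -1.29 ± 0.15. Of 15 acute phase genes, 7 fell and 2 rose, or 9 and 2 adjusted over the list alone, and the kinase PIM1 and the transcription factor STAT3 were those that rose. The NF-kB list had a median of -0.64 and a camera adjusted p of 0.00720, with adjusted p = 0.402 with an estimated correlation. The acute phase list had a median of -0.69, or -0.56 with group means raised to the floor, and a camera adjusted p of 0.0466, with adjusted p = 0.519 with an estimated correlation. The acute phase call was lost in 9 of 20 alternatives, over a range of 0.0064 to 0.492, including without DMSO replicate 1 (adjusted p = 0.0905) and CU27 replicate 2 (adjusted p = 0.145).

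Further large falls lay outside the lists past camera. KRT23, a keratin, fell by 2.93 ± 0.43. The fly four-jointed homologue FJX1, a member of the YAP/TEAD list, fell by 2.36 ± 0.29. APH1B, a gamma-secretase subunit, fell by 2.16 ± 0.27, and its 6 probe sets ran from -2.16 to -0.68. CA4, a carbonic anhydrase, and the complement regulator C4BPA had log2 changes of -2.09 ± 0.27 and -2.05 ± 0.33. NOX1, a superoxide-generating oxidase, and SLC6A14, an amino acid transporter, lay below the floor in CU27 and fell at least 8.51-fold and at least 4.52-fold by the probe set used, while their weakest other probe sets had log2 values of -2.92 and -1.95. The cell cycle inhibitor CDKN1A at -0.01 ± 0.18 and the haem oxygenase HMOX1 at -0.41 ± 0.23 were not past the test. HMOX1 had an adjusted p of 0.0463 without DMSO replicate 2, over a range of 0.0463 to 0.965.

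The other 17 lists tested in Huh7.5.1 did not pass camera, with adjusted p from 0.0530 to 0.915. In the oxidative stress list under NRF2, 8 of 25 genes rose and 1 fell, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0980). Among p53 targets 2 of 20 rose and 6 fell, or 2 and 7 adjusted over the list alone (camera adjusted p = 0.141). Among YAP/TEAD targets 1 of 14 rose and 5 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0530). In immediate early genes 4 of 21 fell and 0 rose, in both counts. In fatty acid oxidation 3 of 15 rose and 5 fell, or 3 and 7 adjusted over the list alone, and in hepatocyte metabolism 2 of 12 rose and 4 fell, or 2 and 5. Fatty acid synthesis had 3 of 15 that rose and 4 that fell, PXR/CAR drug metabolism 1 and 2 of 9, oxidative phosphorylation 4 and 2 of 27, and proteasome genes 4 and 2 of 24, the same adjusted over the list alone. Cytosolic ribosomal proteins had 2 that rose and 1 that fell of 30, or 0 and 0 adjusted over the list alone. Wnt targets had 1 and 1 of 11, epithelial junctions 2 and 1 of 13, and mesenchymal genes 2 and 1 of 16, the same adjusted over the list alone. Apoptosis effectors had 1 that rose and 3 that fell of 15, or 2 and 3 adjusted over the list alone, and apoptosis inhibitors 1 and 1 of 8, or 1 and 2. Leukocyte markers had 2 that rose and 1 that fell of 5, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.618, fry 0.00554), and the fibroblast and endothelial lists had 3 tested genes each and were too small to test. In fatty acid synthesis and in apoptosis effectors the median was above 0 and the mean and test were below it, and in Wnt targets and apoptosis inhibitors the mean was above 0 and the median and test below.

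**Figure D3:**
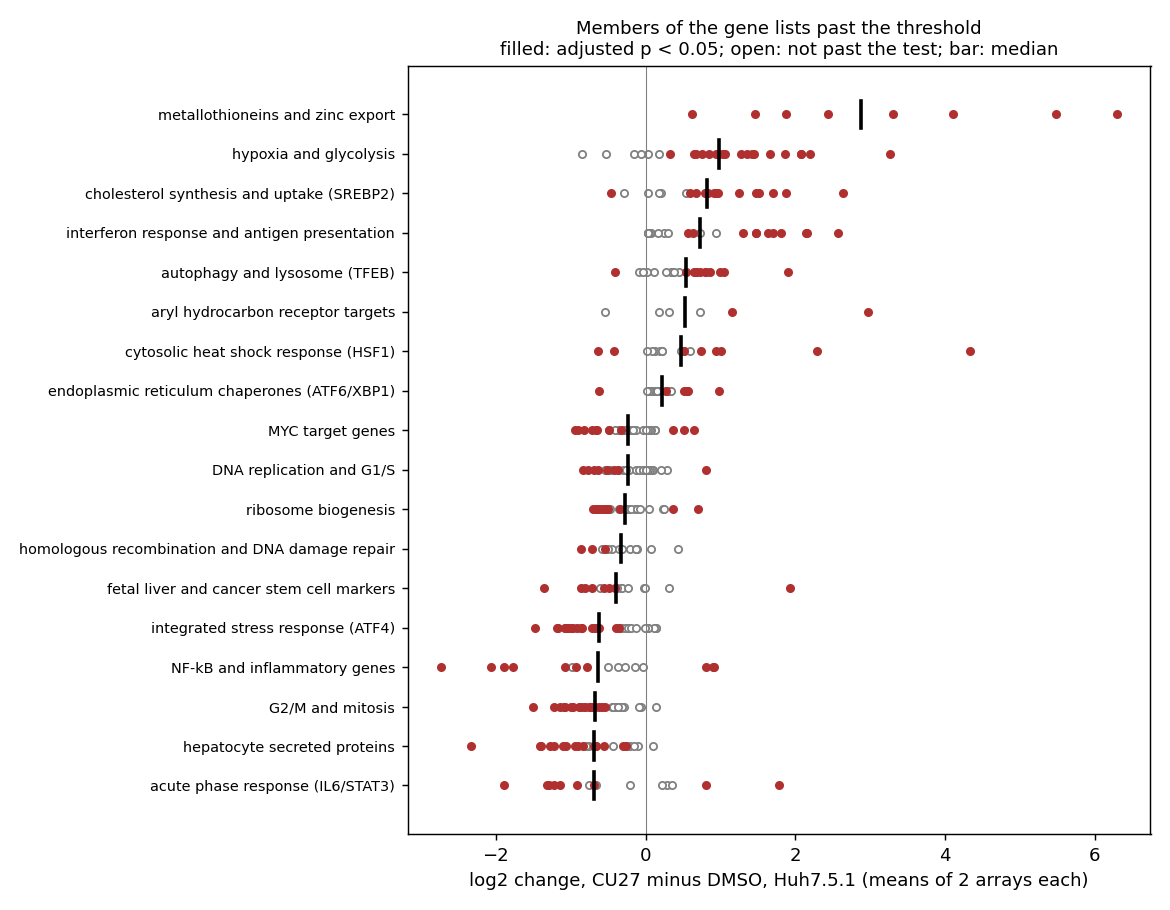
Log2 change with CU27 in Huh7.5.1 (x axis) of the tested members of the 18 lists past camera (y axis), with a point per gene, filled where the gene passed the test, and a bar at the list median. Medians run from -0.69 in secreted liver proteins and acute phase genes to 2.88 in metallothioneins.

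Huh7.5.1 and Hep3B differed widely in DMSO, the background of the CU27 comparison. Signals of Huh7.5.1 arrays were higher over all probe sets, by 0.417 at the median, so the differences below are given relative to that shift, while adjusted p refers to the deposited scale. The median difference was 0.42 in probe sets under log2 4, 0.15 in those over 10 and 0.22 over the tested genes, so the shift subtracted exceeds the median difference of all but the dimmest probe sets. The 3′ to 5′ difference moved with the line too, being 2.28 and 1.60 for ACTB and 0.430 and 0.320 for GAPDH in Hep3B, against 0.94 and 1.06 and against 0.0670 and 0.0935 in Huh7.5.1. The calcium-binding protein S100P and the secreted trypsin inhibitor SPINK1 were higher in Huh7.5.1 by 5.98 ± 0.11 and 5.55 ± 0.12, and the tetraspanin TSPAN8 by 4.93 ± 0.31. GSTP1, a glutathione transferase, the collagen COL2A1, the secretory disulfide isomerase AGR2 and the reductase PTGR1 lay below the floor in Hep3B and were at least 185-fold, 79.2-fold, 45.4-fold and 32.7-fold higher on the deposited scale. XIST, the RNA that silences an X chromosome, also lay below the floor in Hep3B and was at least 74.8-fold higher on the deposited scale. These bounds hold for the probe set used. The weakest other probe sets of GSTP1, XIST and AGR2 had log2 differences of 2.10, 5.19 and 0.63 on the deposited scale. Relative to the shift these were 1.68, 4.78 and 0.21. The galectin LGALS1 was lower in Huh7.5.1 at -5.13 ± 0.25, the histidine-degrading HAL at -5.05 ± 0.19, MAGED1 at -5.05 ± 0.14 and the fetal protein DLK1 at -5.01 ± 0.31. The keratin KRT19, the lipid regulator ANGPTL8, the splicing factor ESRP1 and the prostaglandin synthase PTGDS lay below the floor in Huh7.5.1 and were at least 46.8-fold, 23.9-fold, 19.6-fold and 17.5-fold lower on the deposited scale. The weakest other probe sets of DLK1 and ESRP1 had log2 differences of -1.02 and -3.97 on that scale. Limma passed 7283 of 11383 genes, 4671 higher and 2612 lower in Huh7.5.1. The split was 3108 higher and 4009 lower after quantile normalization and 2648 higher and 4659 lower after centring each array on its median.

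Between the lines, 8 of 35 lists passed camera and 0 passed with an estimated correlation. Genes of ATF4 (29 of 31 higher and 1 lower), of p53 (15 of 20 higher and 2 lower) and of NRF2 (18 of 25 higher and 1 lower) were higher in Huh7.5.1 on the deposited scale. The ATF4 genes CTH, SLC3A2 and STC2 were higher by 3.19 ± 0.14, 2.20 ± 0.11 and 3.14 ± 0.15 relative to the shift, the p53 targets GADD45A and PLK2 by 1.92 ± 0.11 and 2.69 ± 0.17, and the NRF2 targets GCLM, NQO1 and ME1 by 2.91 ± 0.14, 3.32 ± 0.18 and 1.85 ± 0.13. PMAIP1, a p53 target that promotes apoptosis, lay below the floor in Hep3B and was at least 21.4-fold higher on the deposited scale. Metallothioneins (7 of 8 higher), NF-kB genes (13 of 16 higher) and YAP/TEAD targets (11 of 14 higher) had 0 members lower on the deposited scale, which the shift favours. MT2A and MT1X, whose single levels are uncertain, were higher by 3.07 ± 0.21 and 2.99 ± 0.28 relative to the shift. CXCL2, CXCL5, CXCL3 and the tissue factor F3 were higher by 2.01 ± 0.15, 2.16 ± 0.19, 2.63 ± 0.30 and 1.78 ± 0.15 relative to the shift. MT1F, ANKRD1 and TGFB2 lay below the floor in Hep3B and were at least 12.6-fold, 1.52-fold and 1.32-fold higher on the deposited scale. Relative to the shift of 1.33-fold the bound of ANKRD1 was 1.14-fold, and the bound of TGFB2 did not exceed the shift. Their values of 2.45 ± 0.19 and 0.89 ± 0.17 relative to the shift rest on Hep3B signal below the floor. Other probe sets of MT2A, TGFB2 and CPS1 had weaker differences of 0.37, 0.39 and -0.32 on the deposited scale, and the weakest of MT1F had 3.33. Cholesterol synthesis genes (16 of 20 lower and 1 higher) and hepatocyte metabolism genes (7 of 12 lower and 1 higher) were lower in Huh7.5.1 on the deposited scale. SQLE, the thiolase ACAT2 and INSIG1 had values of -2.81 ± 0.12, -1.61 ± 0.10 and -2.62 ± 0.19 relative to the shift. The glucuronyltransferase UGT2B7 and the urea cycle enzyme CPS1, below the floor in Huh7.5.1, were at least 7.38-fold and 3.64-fold lower on the deposited scale. Adjusted over the list alone, the counts were the same, except 30 of 31 ATF4 genes higher. Camera adjusted p was 7.21e-06 for ATF4, 0.0182 for p53, 0.00201 for NRF2, 0.0355 for metallothioneins, 0.0218 for NF-kB, 0.0331 for YAP/TEAD, 7.21e-06 for cholesterol and 0.00202 for hepatocyte metabolism. These were adjusted p = 0.578 with an estimated correlation for p53, ATF4, NF-kB, YAP/TEAD, cholesterol and hepatocyte metabolism, and adjusted p = 0.640 with an estimated correlation for NRF2 and metallothioneins. The metallothionein call was lost without CU27 replicate 1 (adjusted p = 0.0703) or CU27 replicate 2 (adjusted p = 0.0702) of Huh7.5.1, over a range of 0.00252 to 0.0744, and the YAP/TEAD call without Hep3B DMSO replicate 2 (adjusted p = 0.0527), over a range of 0.00237 to 0.0958. Each of the other 27 lists had a camera adjusted p above the threshold.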

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

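Tests of the Hep3B columns, of the scaling behind the metallothionein rise and of the scale of the lines were chosen after the results were seen, and the test of shared metallothionein signal was written before but read for each gene, and split at the floor, only after the values were known.

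Both Hep3B CU27 columns were exact linear functions of the Hep3B DMSO columns at 100% of probe sets, a signal in columns that the comparisons left out, except in the alternative that fitted all 8. The matching combination of columns had an SD of 0.36 over probe sets in Huh7.5.1 and of 0 in Hep3B, which argues against separate arrays that happen to be similar. In the 6 other columns 100% of values were the shortest text of a 32-bit number, against 54.1% and 58.0% in these columns. The values may have been filled in by extrapolation from the DMSO columns, at what step is not given in the sources used here. No biological explanation was tested, and a fit of all 8 columns would call 3528 genes changed by CU27 in Hep3B (2445 higher, 1083 lower) with no measured treatment behind them.

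Metallothioneins rose in CU27-treated Huh7.5.1. Scaling of the arrays is argued against, since the median of metallothionein genes stayed at 3.70 after quantile normalization while the median of all genes was 0.02. Signal shared between near-identical probes is left undecided as a cause. The test took a missing _x_at or _s_at suffix to mark a probe set of 1 gene, but probe sequences were not examined. Among probe sets without an _x_at or _s_at suffix, 4 of 6 genes rose by over 1 log2 beyond the 95% interval, and these 4 were the genes that reached the floor in DMSO. The lowest, MT1X, rose by 2.32 (interval 1.78 to 2.87). The 4 probe sets of MT1DP and MT1IP lay below the floor, with a median of 0.07, so the median over all 8 was 1.22 with a median absolute deviation of 1.83. How much signal single members share stays open. A true rise of several members with CU27 treatment is a candidate explanation and a hypothesis from the same arrays.

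More genes were higher than lower in Huh7.5.1 than in Hep3B in DMSO. Background probe sets without a human target were higher in Huh7.5.1 by 0.52 at the median, so arrays of the lines may lie on different scales. A single shift of all signals is argued against, since the median difference was 0.42 in probe sets under log2 4, 0.32 at 4 to 6, 0.36 at 6 to 8, 0.23 at 8 to 10 and 0.15 over 10. Quantile normalization turned the split to 3108 higher and 4009 lower. Scale, RNA integrity (ACTB 3′ to 5′ difference 2.28 and 1.60 in Hep3B, 0.94 and 1.06 in Huh7.5.1) and line follow the same split of the arrays, so RNA quality and a true difference between the lines stay open and untested.

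Probe sets without a gene in the annotation also passed the test with CU27 in Huh7.5.1, 252 of 1226 (126 rose, 126 fell). Of 1008 probe sets with several genes, 231 passed (102 rose, 129 fell).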

How the results depend on the processing

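The fit of all 8 columns was chosen as an alternative after the data were seen. It called 3034 genes with CU27 in Huh7.5.1 and 7514 between lines. Over the other alternatives that kept every array, genes changed by CU27 numbered 2283 to 3567. Between lines, a floor at the 75th percentile left 4848 genes, fewer genes being tested, and no filter gave 10641 (7517 higher, 3124 lower). Without single arrays the CU27 count ran from 900 (DMSO replicate 2) to 2923 (CU27 replicate 1). With an estimated correlation 0 lists passed in the CU27 comparison and 0 between lines, for a cause that was not tested. Between lines fry passed 24. Unlike camera, fry does not compare a list with the other genes, whose median was 0.22 higher in Huh7.5.1. Fetal liver markers passed fry upward (adjusted p = 0.0114), though camera placed them downward (adjusted p = 0.804). The fry count between lines therefore includes effects of the shift, to an extent not tested. Of the 72 genes named with CU27, 51 kept direction and call in every alternative that tested them, as did all 39 named between lines. Apart from the estimated correlation, 10 of the 18 CU27 lists and 6 of the 8 lists between lines kept theirs wherever they were tested. Without _x_at and _s_at probe sets some named genes were not tested, and 35 of the 39 between lines were. The metallothionein list had fewer than 5 tested genes there, so its call was not checked against these probe sets. The mean of all probe sets ended the call of IGF2BP1 (adjusted p = 0.0621, range 0.00101 to 0.0621), and leaving out _x_at and _s_at probe sets ended those of PROM1 (adjusted p = 0.0598, range 0.0018 to 0.0598) and CXCL8 (adjusted p = 0.0545, range 5.57e-05 to 0.0545).

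RRP1B turned to 0.40 without _x_at and _s_at probe sets, another probe set being used, and DDIT3 to 0.014 with the mean of all probe sets. Without single arrays the log2 change ran from -0.24 to 0.11 for MKI67, -0.14 to 0.12 for CDKN1A, -0.35 to 0.34 for DDIT3 and -0.49 to 0.025 for AFP, none past the test in the full fit. The replicate block called 3567 genes and 20 lists with CU27, and CYP1A1 passed under it (0.73, adjusted p = 0.004, range 0.004 to 0.613 over alternatives). The block adds terms to a fit with 3 residual degrees of freedom, so its estimate of the spread rests on fewer. Same-numbered Huh7.5.1 deviations correlated at 0.179 over genes, from 2 pairs, which cannot tell whether the arrays were paired. The labels describe no pairing, so the numbers are not treated as such in the main fit. CU27 alternatives for Hep3B were not run, there being no measured treatment. Signal below log2 6.11 is treated here as not told from background. That floor is a percentile of all values and was not measured from background probe sets.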

Other observations

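The lists of further hypoxia, lysosome and interferon genes, and their tests, were written after the fixed lists had passed but before these genes' values were seen.

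Further targets of the hypoxia-inducible factor, none of them in the fixed lists, rose in CU27-treated Huh7.5.1. Of 23 tested genes, 15 rose and 0 fell, or 17 changed adjusted over the list alone, among them the prolyl hydroxylase P4HA2 and the oxidoreductase ERO1A, chosen as examples after their values were seen. The median was 0.70 and the camera adjusted p over the 3 added lists was 5.4e-09, with adjusted p = 0.0553 with an estimated correlation. A wider rise of HIF targets may therefore accompany CU27 treatment in this line, as a hypothesis from the same arrays.

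Further lysosome genes had a median of 0.25, with 9 of 27 that rose and 1 that fell, or 10 changed adjusted over the list alone. The camera adjusted p was 0.00443, with adjusted p = 0.228 with an estimated correlation. Further interferon-stimulated genes had a median of 0.28, with 3 of 19 that rose and 0 that fell, or 1 changed adjusted over the list alone. Their camera adjusted p was 0.0257, with adjusted p = 0.414 with an estimated correlation, and fry gave 0.119. A wider rise of either group stays a hypothesis and may rest on a few genes.

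Few markers of other cell types reached the floor. In Huh7.5.1 DMSO and CU27 these were 2 and 2 of 11 fibroblast markers, 3 and 2 of 10 endothelial markers and 3 and 3 of 12 leukocyte markers. The lysosomal macrophage marker CD68 rose by 2.25 with CU27.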
